A study of Caenorhabditis elegans with 20 samples.

How the data were processed

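RNA was sequenced from whole C. elegans of the L4 stage. Per the labels' protocols, animals grew in liquid culture from synchronized L1 larvae, received F17 or the solvent DMSO for the 4 h before harvest, and were extracted in Trizol with column purification and DNase treatment. Poly(A) RNA was made into strand-specific libraries. The 20 libraries fall into 4 groups of 5: wild type with DMSO, wild type with F17, nhr-131 with DMSO and nhr-131 with F17. F17 was used at 2.5 µM and DMSO at 0.1%. The deposited values are whole counts of reads per gene, 28301 genes by 20 libraries, made with TopHat2 for alignment and HTSeq for counting per the submitters' processing notes. Versions of those tools, the genome build and the gene annotation are not given in the sources used here, so no coordinates are printed. The counts carried no normalization. Every column of the table was used.

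Gene names are those of the table. The RefSeq gene table of assembly WBcel235 was used only for names, chromosomes and which genes neighbour each other, and 13517 of the tested genes matched it. In 10 cases a row name reads as a date, and all 10 were tested under the name as given. No pair of libraries in a group was a copy of another: the lowest chi-square per degree of freedom between libraries of a group was 22.7.

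Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group (minimum count 10), which left 13795 genes. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with 4 group means was fitted to all 20 libraries with robust dispersion, with 16 residual degrees of freedom. The 6 contrasts were tested by edgeR's quasi-likelihood F-test: the effect of F17 in wild type, the effect of F17 in nhr-131, the difference of these effects, nhr-131 against wild type in DMSO, nhr-131 against wild type in F17, and the mean effect of F17 over both genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 estimates of that model, and the standard error (SE) is the absolute log2 fold change divided by the square root of F. CPM are computed with TMM-scaled library sizes and given as mean ± SD. The p-values measure the spread between these libraries, which the labels describe as independent biological replicates.

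Genes were named by a rule. It took nhr-131 and up to 4 called members of each gene list. It also took the 8 called genes with the largest rise and the 8 with the largest fall, among genes with a mean log2 CPM of at least 1. Their groups had to show no overlap of libraries, except for the difference of effects. Genes named outside the rule are stated as chosen after their values were seen. Of 44 lists of genes fixed by name, covering detoxification families, lipid and energy metabolism, stress responses, tissues and developmental stage, 43 had at least 5 tested members. The list of pals genes had 0 members in the table. There were 29 list names that the table does not hold under that name. Lists and 107 classes of genes sharing a name prefix (at least 10 tested members) were tested with camera at an inter-gene correlation of 0.01, adjusted over lists or over classes within a comparison. Estimated correlations and the rotation test fry were alternatives. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the members of that list only.

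A developmental-age score was computed for each library as the mean z-score of the 11 genes of the L4-to-adult list. The count of nhr-131 was also compared between genotypes by a two-sided permutation test with 100000 resamples. Ratios of genes with few counts in DMSO were scaled by the total counts of the groups and carry 95% exact intervals, which cover counting error only. The size of the response in nhr-131 was the median genotype difference over genes called for the mean effect, signed by the direction of that effect, with a permutation p from exchanging genotypes within a treatment in 100 draws. Counts of calls were compared with those from 100 splits of the libraries, the real split included.

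The procedure was tested on simulated data made from the real libraries' means and sizes, with 50 genes changed at each fold. Genes were drawn independently of each other, without the variation that the real libraries share across genes. The numbers of unchanged genes called may therefore understate false calls in the real data. For the effect of F17 in wild type (13569 genes), 4 genes were recovered at 1.5-fold, 20 at 2-fold, 33 at 4-fold and 42 at 8-fold, and 2 unchanged genes were called. For the difference of effects (13539 genes) the numbers were 1, 9, 29 and 28, with 3 unchanged genes called. For nhr-131 against wild type in DMSO (13546 genes) they were 5, 16, 37 and 44, with 5 unchanged genes called.

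Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a strict filter (at least 50 counts in 5 libraries), the Wald test of DESeq2 1.42.0 and limma-voom. Further ones were an adjusted p under 0.01, an absolute log2 fold change of at least 1, a fit of only the 10 libraries compared, and leaving out each library in turn. Added after seeing the data were a block by the letter of the column, the age score as a covariate, leaving out 6 libraries that looked younger by expression, and leaving out ribosomal RNA genes. Blocking or pairing by replicate number was left out, because the columns carry letters and nothing maps these to the labels' numbers.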

Results

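Gene counts were obtained for whole C. elegans at the L4 stage in a design of 2 genotypes by 2 treatments. Wild-type animals and animals of a strain mutant for nhr-131, a gene of the nuclear hormone receptor family, received 2.5 µM F17, a compound known here only by this code, or 0.1% DMSO for 4 h. Each of the 4 groups held 5 libraries. Total counts per library ran from 14834464 to 23150429 in wild type with DMSO and from 14403626 to 22465236 in wild type with F17. They ran from 12836432 to 23618692 in nhr-131 with DMSO and from 15836593 to 26908383 in nhr-131 with F17. In the library with the smallest TMM-scaled size 3 counts equal 0.282 CPM. Ribosomal RNA genes took from 2.24% to 27.5% of a library's counts, with group means between 9.88% ± 7.24 and 13% ± 8.4 (SD, n = 5).

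The libraries of a group differed in the developmental-age score, which rests on expression alone. The mean z-score of 11 genes of the L4-to-adult transition was 0.0128 ± 0.665 in wild type with DMSO, -0.289 ± 0.552 in wild type with F17, 0.0166 ± 0.854 in nhr-131 with DMSO and 0.259 ± 0.856 in nhr-131 with F17 (SD, n = 5). In 6 libraries this score was the lowest of their group, and they lay apart on the first component of the variation within groups, which held 53.9% of that variation. These 6 libraries, called younger from here on, were a and c of wild type with DMSO, a and d of wild type with F17, c of nhr-131 with DMSO and c of nhr-131 with F17. Without them the group scores were 0.488 ± 0.192 (n = 3), 0.0977 ± 0.219 (n = 3), 0.396 ± 0.116 (n = 4) and 0.621 ± 0.319 (n = 4) in the same order. The younger libraries of letter c also had low ribosomal RNA shares (2.91%, 3.75% and 2.24%) and high TMM factors (1.3, 1.25 and 1.29). The younger libraries of letters a and d had shares of 14.8%, 22.5% and 5.75%. For letter c, age is thus not separated from the composition of the library or from the letter.

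**Figure D1:**
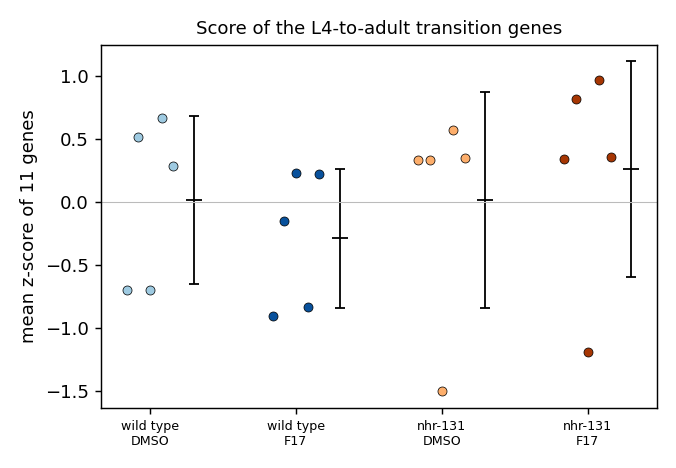
Developmental-age score of each library, the mean z-score of 11 genes of the L4-to-adult transition (y axis), by group (x axis); points are libraries and bars are the mean ± SD (n = 5). Library c of nhr-131 with DMSO lies lowest, at -1.5.

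The nhr-131 transcript itself was nearly lost in the libraries labelled nhr-131. Each of the 10 wild-type libraries held 77 to 196 counts of it, 1402 in all, and each of the 10 mutant libraries 0 to 4 counts, 25 in all. Its level was 7.90 ± 0.746 CPM in wild type with DMSO, 6.56 ± 0.543 in wild type with F17, 0.118 ± 0.0895 in nhr-131 with DMSO and 0.139 ± 0.0986 in nhr-131 with F17 (SD, n = 5), and the mutant total was 1.78% of the wild-type total. A two-sided permutation test of the 10 against 10 libraries gave p = 3e-05 with 100000 resamples. The effect of F17 on nhr-131 did not pass the test in wild type (log2 fold change -0.27, SE 0.34, adjusted p = 0.922) or in the mutant (0.16, SE 0.53, adjusted p = 1). In the mutant the sign of that estimate turned with limma-voom (-0.04) and without the 6 younger libraries (-0.02).

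The first comparison asked which transcripts F17 alters in wild type. Genes of xenobiotic metabolism rose by large factors. cyp-13A6, a cytochrome P450 gene, went from 3.87 ± 3.37 CPM with DMSO to 1150 ± 175 CPM with F17 (SD, n = 5), a log2 fold change of 8.20 (SE 0.60, adjusted p = 2.4e-08). Its paralog cyp-13A4 went from 5.81 ± 7.01 to 1630 ± 312 CPM (8.12, SE 0.87, adjusted p = 5.8e-06); without library a of wild type with DMSO its log2 fold change was 8.83, and without the 6 younger libraries 11.17. cyp-35C1 went from 24.1 ± 3.76 to 1290 ± 194 CPM (5.74, SE 0.20, adjusted p = 5.67e-13) and cyp-14A4 from 1.3 ± 0.464 to 153 ± 33.7 CPM (6.89, SE 0.29, adjusted p = 5.26e-12). The UDP-glucuronosyltransferase gene ugt-20 rose from 3.97 ± 1.35 to 282 ± 37.6 CPM (6.14, SE 0.24, adjusted p = 2.45e-12). Reads shared between close paralogs of these families cannot be excluded, so levels of single paralogs are uncertain. In all, 128 of 13795 genes were called, 106 higher and 22 lower.

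Of the cytochrome P450 genes, whose enzymes oxidise foreign compounds and lipids, 19 of 61 rose, 1 fell and 41 did not pass (22 and 2 adjusted over the list alone). cyp-35A3 rose by 5.93 (SE 0.41, adjusted p = 1.22e-08), and cyp-35D1 fell by 2.08 (SE 0.43, adjusted p = 0.0157). Of the UDP-glucuronosyltransferase genes, which attach sugars to small molecules, 15 of 60 rose and 1 fell (18 and 5 adjusted over the list alone). Among them were ugt-1 at 5.23, ugt-61 at 3.24 and ugt-12 at 2.95 (SE 0.23, 0.19 and 0.15). The list's median was -0.0357 while its mean was 0.706 and camera called it up (adjusted p = 3.43e-18). Of the glutathione S-transferase genes 5 of 32 rose and 0 fell (6 and 0 adjusted over the list alone). They included gst-8 at 6.58 (SE 0.58, adjusted p = 4.02e-07), gst-5 at 3.90 (SE 0.18, adjusted p = 1.76e-11), gst-33 at 2.94 and gst-7 at 2.72. That list had a median of -0.0803, a mean of 0.419 and a camera call up (adjusted p = 0.000213), lost at adjusted p = 0.362 with an estimated correlation.

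Genes of metal stress rose as well. The cadmium-responsive gene cdr-1 rose by 6.50 (SE 0.34, adjusted p = 1.13e-10), cdr-4 by 2.42 (SE 0.23, adjusted p = 1.24e-06) and the metallothionein gene mtl-2 by 2.68 (SE 0.46, adjusted p = 0.00238). These were 3 of 11 members of the osmotic and metal stress list (3 adjusted over the list alone). The list had a median of -0.0411, a mean of 1.05 and a camera call up (adjusted p = 3.81e-08). Of the oxidative stress targets of the transcription factor SKN-1, 3 of 21 rose (3 adjusted over the list alone), all glutathione S-transferase genes: gst-5, gst-7 and gst-6, the last by 1.49 (SE 0.20, adjusted p = 0.000158). The camera call of that list (adjusted p = 0.00029) was lost at adjusted p = 0.437 with an estimated correlation. Of the ABC transporter genes 3 of 29 rose and 1 fell (4 and 2 adjusted over the list alone). pgp-1 at 2.40, pgp-9 at 2.39 and pgp-3 at 0.60 rose and pgp-5 fell by 0.77. All 4 encode P-glycoproteins, which export small molecules. The list as a set was not called (adjusted p = 0.907).

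Other genes that rose were C52A10.2 at 6.04 (SE 0.61, adjusted p = 3.12e-06), the C-type lectin genes clec-206 at 5.29 (SE 0.22) and clec-227 at 1.56 (SE 0.33), and the short-chain dehydrogenase gene dhs-23 at 3.12 (SE 0.32). So did the nuclear hormone receptor genes nhr-142 at 2.91 (SE 0.41) and nhr-11 at 1.36 (SE 0.24), the lipid-binding protein gene lbp-8 at 2.69 (SE 0.50) and F14B4.2, now named hxk-1, at 1.48 (SE 0.15). The falls were smaller: C32H11.4 fell by 2.43 (SE 0.47, adjusted p = 0.00796), F22E5.1 by 1.86 (SE 0.35, adjusted p = 0.00553) and ech-9 by 1.56 (SE 0.35, adjusted p = 0.0338). str-7 fell by 1.24, C06B8.2 by 1.23, F44G3.2 by 1.18 and F42A10.7 by 0.89. clec-51 and the folate transporter gene folt-2 each fell by 0.58. For 38 of the 39 named genes other than nhr-131 the 5 F17 libraries lay wholly beyond the 5 DMSO libraries, 28 above and 10 below; folt-2 overlapped. The rule for naming asked for this of the genes with the largest changes. The calls of folt-2, pgp-3, F42A10.7, clec-51, str-7 and ech-9, all close to the threshold, were lost under 25, 23, 22, 16, 13 and 11 of the 32 or 33 alternative settings, single left-out libraries included. Calls of F44G3.2, pgp-5 and cyp-35D1 were also lost without some single libraries. Examples are F44G3.2 without library c (adjusted p = 0.109) and pgp-5 without b (0.127) of wild type with F17. cyp-35D1 had 0.071 without d of wild type with DMSO.

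The lists of metabolic genes held few calls in wild type. By edgeR 0 of 21 genes of fatty acid synthesis, desaturation and elongation, 0 of 20 acyl-CoA synthetase genes and 0 of 13 lipase and lipolysis genes were called, with 3, 3 and 2 at unadjusted p under 0.05 and 0 by DESeq2 or limma-voom in each list. ech-9 was the single call among 33 genes of beta-oxidation. In the heat shock response list 0 of 11 genes were called by edgeR, DESeq2 or limma-voom, and 0 were at unadjusted p under 0.05. Lists of germline, sperm and oocyte genes leaned to one side without a called gene by edgeR. The medians were 0.992 for 30 major sperm protein genes (11 at unadjusted p under 0.05, 0 by DESeq2), 0.861 for 23 other sperm genes (6 and 0), 0.936 for 23 oocyte and eggshell genes (11 and 1) and 0.533 for 31 germline genes (3 and 0). Their camera calls (adjusted p = 2.38e-08, 3.14e-05, 1.66e-08 and 7.9e-05) were lost at adjusted p = 0.783, 0.437, 0.437 and 0.917 with an estimated correlation. The age score dropped by 0.302 with F17 in wild type. With this score as a covariate the medians were 1.22, 0.937, 1.03 and 0.478, with 2 major sperm protein and 2 oocyte genes called higher (adjusted p = 0.606 and 0.792 for these 2 lists with an estimated correlation). Camera also called nuclear hormone receptor genes down (median -0.173, adjusted p = 0.0017), the propionate and methionine list down (-0.169, 0.00798), mitochondrial-encoded genes down (-0.368, 0.018) and muscle markers down (-0.154, 0.03). With an estimated correlation these had adjusted p = 0.759, 0.783, 0.917 and 0.783.

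Of the 13 lists that camera called in wild type, 3 held with an estimated correlation: the P450 genes (adjusted p = 8.8e-06), the UDP-glucuronosyltransferase genes (adjusted p = 0.000391) and the osmotic and metal stress genes (adjusted p = 0.0446). The count of 128 genes was 197 with DESeq2's Wald test (144 higher, 53 lower), 254 with the age score as a covariate (185 and 69) and 906 without the 6 younger libraries (550 and 356), of which 128, 128 and 123 were among the 128. Those 6 libraries were picked on the variation within groups, so leaving them out lowers the spread by construction. The remaining wild-type libraries also still differed in the age score, 0.488 ± 0.192 with DMSO and 0.0977 ± 0.219 with F17 (SD, n = 3). The 906 calls may hold part of both. The 22 lower genes were 7 in a fit of only these 10 libraries, and 10 to 37 without single libraries, the ends being library b of wild type with F17 and c of wild type with DMSO.

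**Figure D2:**
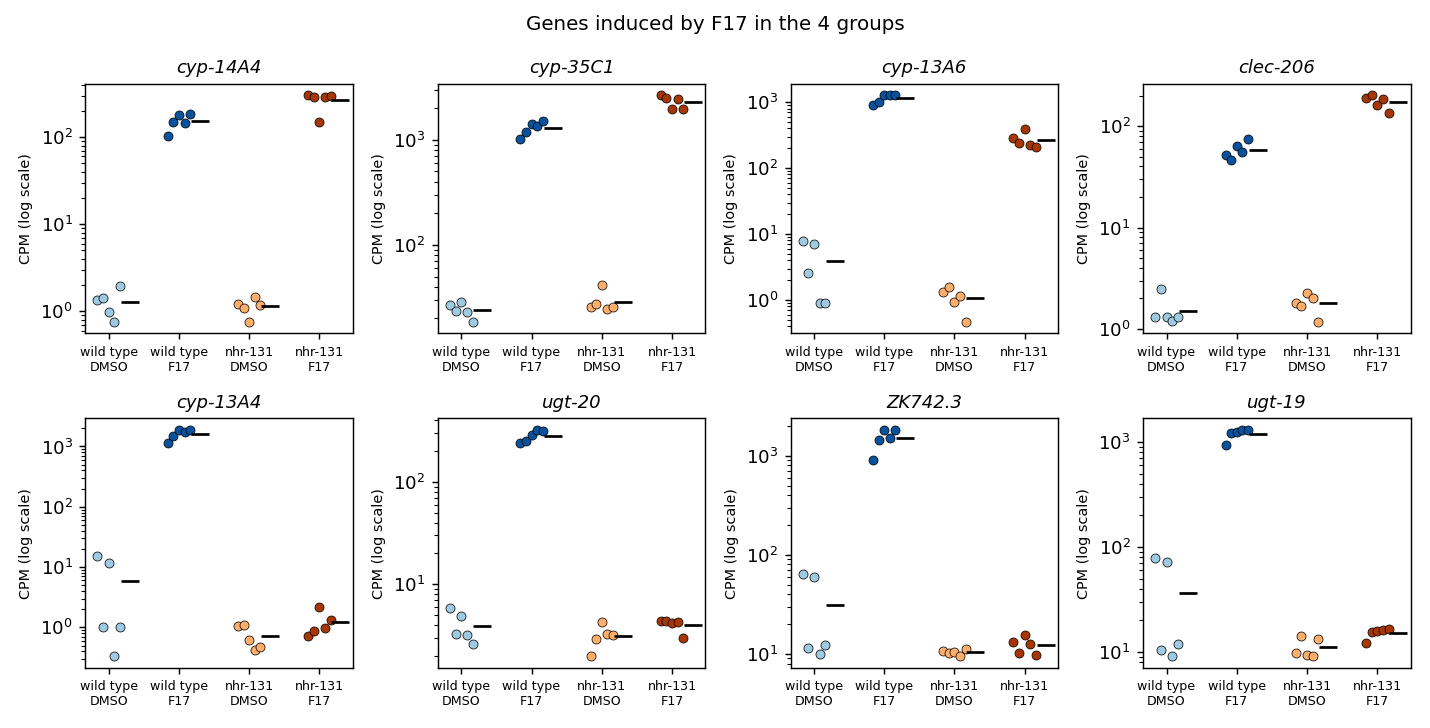
CPM of 8 genes in each library (y axis, log scale) by group (x axis); points are libraries and short lines are group means (n = 5). cyp-14A4, cyp-35C1, cyp-13A6 and clec-206 were high with F17 in both genotypes, while cyp-13A4, ugt-20, ZK742.3 and ugt-19 stayed between 1.21 and 15.2 CPM on average in nhr-131 with F17.

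The second comparison asked what F17 does in nhr-131 animals. Much of the same detoxification response was present. cyp-13A6 rose from 1.08 ± 0.413 to 269 ± 72.2 CPM (SD, n = 5), a log2 fold change of 7.95 (SE 0.61, adjusted p = 6.22e-08). cyp-14A4 rose from 1.14 ± 0.254 to 266 ± 64.6 CPM (7.86, SE 0.31, adjusted p = 2.16e-12) and cyp-35C1 from 28.9 ± 7.10 to 2310 ± 325 CPM (6.32, SE 0.20, adjusted p = 1.59e-13). clec-206 rose from 1.79 ± 0.408 to 175 ± 26.6 CPM (6.58, SE 0.24, adjusted p = 5.66e-13) and cdr-1 from 1.3 ± 0.626 to 141 ± 8.33 CPM (6.70, SE 0.35, adjusted p = 1.91e-10). In all, 66 genes were called, 65 higher and 1 lower, the last being lem-3, which lies outside the rule for naming and was chosen after its value was seen.

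In nhr-131, 14 of 61 P450 genes rose and 0 fell (19 and 0 adjusted over the list alone). Among them were cyp-35A4 at 7.26 (SE 0.67; 9.32 without library c of nhr-131 with DMSO), cyp-35A3 at 6.85 (SE 0.43) and cyp-35A5 at 5.29 (SE 0.37). Of the UDP-glucuronosyltransferase genes 11 of 60 rose and 0 fell (17 and 0 adjusted over the list alone). They included ugt-1 at 3.88, ugt-61 at 3.31, ugt-16 at 2.31 and ugt-22 at 2.07. Of the glutathione S-transferase genes 3 of 32 rose (4 adjusted over the list alone). They were gst-8 at 3.82 (SE 0.82, adjusted p = 0.0382), gst-33 at 3.31 (SE 0.27, adjusted p = 1.86e-07) and gst-5 at 2.55 (SE 0.17, adjusted p = 8.85e-09). cdr-1 was the 1 member of the metal and osmotic stress list that rose (2 adjusted over the list alone). C52A10.2 rose by 6.68 (SE 0.62; 8.3 without library c of nhr-131 with DMSO), lbp-8 by 3.94 (SE 0.53), and pgp-9 by 2.62 (SE 0.37). nhr-142 rose by 2.03 (SE 0.41), dhs-23 by 1.82 (SE 0.31), dhs-14 by 1.06 (SE 0.23) and F08G5.6, the infection response gene now named irg-4, by 0.88 (SE 0.14). For 21 of the 22 named genes other than nhr-131 the 5 F17 libraries lay above all 5 DMSO libraries, and dhs-14 overlapped; the rule asked for this of the largest changes. The calls of gst-8 and dhs-14 were lost under 18 and 12 of 33 alternative settings.

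Camera called 14 lists in nhr-131, and 4 held with an estimated correlation: the P450 genes (adjusted p = 5.99e-76, and 3.42e-08 with the estimate), the UDP-glucuronosyltransferase genes (4.71e-35 and 5.75e-06), the glutathione S-transferase genes (2.84e-08 and 0.037) and the osmotic and metal stress genes (3.28e-10 and 0.0115). The SKN-1 target list, with 1 of 21 genes higher (2 adjusted over the list alone), was called up at adjusted p = 0.000672 and had adjusted p = 0.393 with an estimated correlation. The other calls were lost at adjusted p between 0.393 and 0.949 with an estimated correlation. They were molting cycle genes (median -0.294, adjusted p = 0.000224), DNA replication genes (-0.245, 0.000672), cytosolic ribosomal protein genes (-0.171, 0.00211), and hypodermis genes (-0.223, 0.0247). The rest were histone genes (-0.291, 0.0377), hypoxia response genes (-0.151, 0.0459), mitochondrial-encoded genes (0.375, 0.00703), major sperm protein genes (0.151, 0.00642) and oocyte genes (0.165, 0.0461). The call of the major sperm protein genes turned to the other direction without library c of nhr-131 with DMSO (adjusted p = 0.655), and that of the ribosomal protein genes without library a of nhr-131 with DMSO (adjusted p = 0.191). The count of 66 genes was 116 with the age score as a covariate and 140 without the 6 younger libraries, of which 66 and 65 were among the 66.

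The third comparison tested whether the effect of F17 differed between genotypes, and thus which induced genes responded differently in nhr-131. A part of the response was nearly absent in the mutant. ugt-20, which went from 3.97 to 282 CPM in wild type, was at 3.13 ± 0.818 CPM with DMSO and 4.06 ± 0.608 CPM with F17 in nhr-131 (difference of log2 fold changes -5.79, SE 0.30, adjusted p = 1.34e-09; n = 5 per group). cyp-13A4 was at 0.731 ± 0.309 and 1.21 ± 0.575 CPM in nhr-131 (difference -7.35, SE 1.1, adjusted p = 0.0029), although its paralog cyp-13A6 was induced in both genotypes (difference -0.25, SE 0.68, adjusted p = 1). Without the 6 younger libraries the effect on cyp-13A6 in wild type was 9.75 in place of 8.20, so its small difference rests in part on those libraries. ZK742.3 went from 31.6 ± 27.7 to 1510 ± 380 CPM in wild type and from 10.4 ± 0.632 to 12.2 ± 2.29 CPM in nhr-131 (difference -5.34, SE 0.64, adjusted p = 0.000157). ugt-19 went from 36.7 ± 35.9 to 1210 ± 151 CPM in wild type and from 11.1 ± 2.42 to 15.2 ± 1.76 CPM in nhr-131 (difference -4.58, SE 0.70, adjusted p = 0.00319).

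In all, 34 genes differed, 30 with a lower effect in nhr-131 and 4 with a higher one. Among the 30 were also swt-6, of the SWEET sugar transporter family (difference -4.56, SE 0.49, adjusted p = 4.56e-05), C53B4.3 (-3.56, SE 0.22, adjusted p = 1.03e-08), F12E12.11 (-2.97, SE 0.39, adjusted p = 0.000588), cyp-13A8 (-3.92, SE 0.77, adjusted p = 0.036) and cyp-13A5 (-3.16, SE 0.65, adjusted p = 0.0478). ugt-12 (-2.33, SE 0.20), gst-7 (-2.38, SE 0.43), cdr-4 (-1.59, SE 0.31), gst-5 (-1.35, SE 0.23) and F14B4.2 (-1.13, SE 0.21) belonged to them as well. The 4 genes with a higher effect in nhr-131 were cyp-35B2 (2.26, SE 0.37, adjusted p = 0.00707), E02C12.6 (2.09, SE 0.43, adjusted p = 0.0422), F59B1.8 (1.98, SE 0.40, adjusted p = 0.0387) and ugt-26 (0.83, SE 0.15, adjusted p = 0.0196). For ugt-26 the sign reflects no larger rise. It fell in wild type (-0.88, SE 0.11, adjusted p = 3.61e-05) and was not called in nhr-131 (-0.04, SE 0.11). Without the 6 younger libraries the difference was -10.74 for cyp-13A4, -7.09 for ZK742.3, -6.51 for ugt-19 and -5.12 for cyp-13A5. The calls of cyp-13A5, E02C12.6, F59B1.8 and cdr-4 were lost under 23, 22, 21 and 15 of 32 alternative settings and that of cyp-13A8 under 17 of 31. cyp-35B2 reached 1.88 ± 0.467 CPM with F17 in wild type and 8.89 ± 0.220 CPM in nhr-131.

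Of the 106 genes higher with F17 in wild type, 57 were also called higher in nhr-131, where independent calls would share 0.499, and 29 had a significantly smaller effect in nhr-131. Picking the 106 genes on the wild-type effect by itself pushes their difference towards a smaller effect in nhr-131. A group of 47 genes was called in both genotypes without a difference, with a median log2 fold change of 2.94 in wild type and 3.24 in nhr-131; it held 12 P450, 8 UDP-glucuronosyltransferase and 2 glutathione S-transferase genes. With F17, 4 of the 47 were lower in nhr-131 than in wild type and 5 higher. One of the 4, gst-8, reached 102 ± 14.1 CPM with F17 in wild type and 1.07 ± 0.207 CPM in nhr-131 (-6.57, SE 0.58, adjusted p = 8.95e-07), from 0 to 3 counts per library with DMSO there. Its difference of effects was -2.76 (SE 1.39, adjusted p = 1), so whether its response is kept is undecided. Another 21 genes had a smaller effect and no call in nhr-131 (medians 2.83 and 0.34; 3 P450, 3 UDP-glucuronosyltransferase and 1 glutathione S-transferase gene), and 8 had a smaller effect but were still called (3.39 and 1.37). For 28 genes there was neither a call in nhr-131 nor a difference (1.68 and 0.51), which leaves them undecided, and 2 had a larger effect in nhr-131 (1.67 and 3.79). Of the 22 genes lower in wild type 0 were called in nhr-131 by edgeR, DESeq2 or limma-voom, and 8 were at unadjusted p under 0.05 there. By edgeR 1 of the 22, ugt-26, was called for the difference between genotypes.

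By list, 3 of 61 P450 genes had a lower and 1 a higher effect in nhr-131 (4 and 1 adjusted over the list alone). So had 5 and 1 of 60 UDP-glucuronosyltransferase genes (7 and 5 adjusted over the list alone). The 1 with a higher effect was ugt-26, which fell in wild type. Of 32 glutathione S-transferase genes 2 had a lower and 0 a higher effect (3 and 0 adjusted over the list alone). Median, mean and test differed in sign for the P450 genes (0.147, -0.0723, up at adjusted p = 0.354) and the UDP-glucuronosyltransferase genes (0.357, 0.0646, down at adjusted p = 0.936). Camera called 12 lists for the difference, and 0 held with an estimated correlation (adjusted p between 0.841 and 0.974) or with fry. They included mitochondrial-encoded genes (median 0.713, adjusted p = 1.33e-06), DNA replication genes (-0.405, 1.95e-05), oocyte genes (-0.832, 9.52e-05) and ribosomal protein genes (-0.268, 0.000704). They also included major sperm protein genes (-0.843, 0.0014), germline genes (-0.421, 0.00127), other sperm genes (-0.717, 0.00507) and molting genes (-0.328, 0.00248). The others were F-box A genes (0.242, 0.00127), nuclear hormone receptor genes (0.14, 0.00405), muscle markers (0.152, 0.0311) and L4-to-adult genes (1.72, 0.0122). The age score differed by 0.545 in the same contrast. The ribosomal protein call turned direction without library a of nhr-131 with DMSO (adjusted p = 0.923) or without the 6 younger libraries (0.66). The L4-to-adult call did so with the age covariate (0.57), which is made from these same genes and takes out their shift by construction.

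The count of 34 genes was 52 with DESeq2, 61 with the age covariate, 116 without the 6 younger libraries, 14 at an adjusted p under 0.01 and 20 with a block by column letter, of which 34, 34, 33, 14 and 18 were among the 34. It was 22 without library b and 20 without library e of wild type with DMSO, and 19 without c and 22 without e of wild type with F17. It was 20 without b and 22 without d of nhr-131 with DMSO, and 22 without d or without e of nhr-131 with F17.

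**Figure D3:**
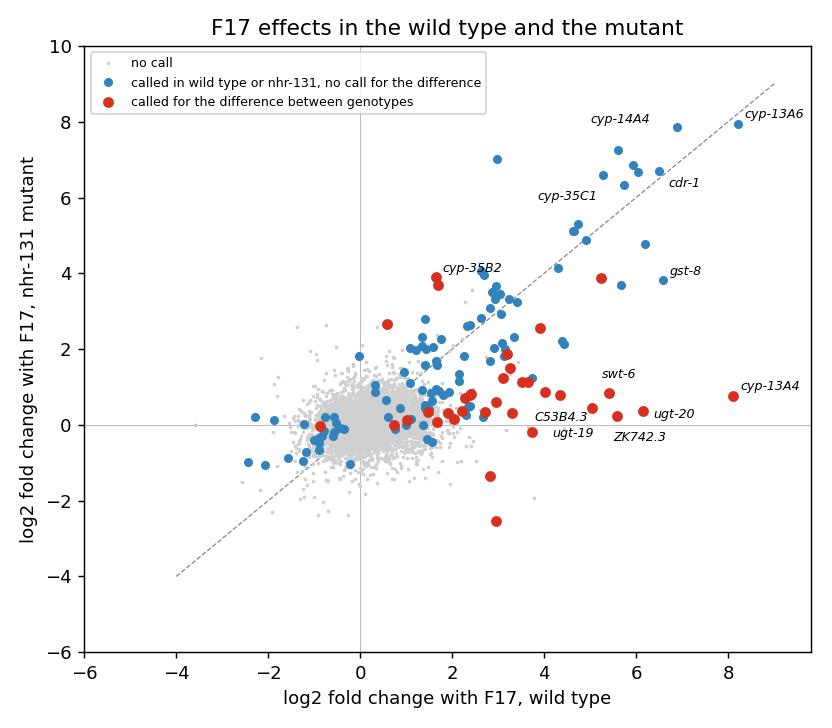
Log2 fold change with F17 in wild type (x axis) against that in nhr-131 (y axis) for 13795 genes; points are genes, grey without a call, blue called in at least 1 genotype, red the 34 that differed between genotypes, and the dashed line marks equal effects. ugt-20 lies at 6.14 and 0.36, and cyp-35B2 at 1.64 and 3.90.

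The size of the response was compared over the 142 genes called for the mean effect of F17 over both genotypes (119 higher, 23 lower). Their median log2 fold change, signed by the direction of the mean effect, was 2.15 in wild type and 1.07 in nhr-131. The difference signed by the mean effect had a median of -0.41, with 90 genes smaller and 52 larger in nhr-131 (permutation p = 0.03, 3 of 100 draws as far from 0; jackknife SE 0.366). The jackknife SE over libraries was nearly as large as that median, which was -0.213 with the age covariate and ran from -0.568 to -0.188 without single libraries, the last without c of nhr-131 with DMSO. Across the 13795 genes, which are not independent replicates, the effects in the 2 genotypes had Pearson r = 0.423 (jackknife SE 0.231) and Spearman rho = 0.202, with the same sign for 55.3% of genes. That r was 0.224 without library c of nhr-131 with F17 and 0.26 without the 6 younger libraries. The count of 142 genes was 270 with the age covariate (163 higher, 107 lower) and 496 without the 6 younger libraries (252 and 244), of which 142 and 139 were among the 142.

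The fourth comparison asked how nhr-131 animals differ from wild type without the compound. Of 13795 genes 4 were called by edgeR, 3 lower and 1 higher, with 575 at unadjusted p under 0.05. The lower genes were nhr-131 itself (log2 fold change -5.93, SE 0.46, adjusted p = 2.85e-07), ZK228.3 and ZK228.4. ZK228.4 was at 44.5 ± 5.44 CPM in wild type and 0.0393 ± 0.0681 CPM in nhr-131 with DMSO (SD, n = 5; adjusted p = 1.99e-10). It had 3 counts against 4223, a ratio of 0.0773% after scaling to equal total counts, as for the next 2 genes (95% interval 0.0159% to 0.226%). ZK228.3 was at 30.8 ± 9.36 and 0.0507 ± 0.0697 CPM (adjusted p = 5.44e-09), 5 counts against 3024 and a ratio of 0.18% (0.0584% to 0.42%). nhr-131 had 11 counts against 752, a ratio of 1.59% (0.791% to 2.86%). W02G9.3, now named thum-1, was higher in nhr-131, at 12.5 ± 2.24 against 0.883 ± 0.465 CPM (3.79, SE 0.29, adjusted p = 2.49e-07). The reads of W02G9.3 are uncertain in origin, because the gene lies within kel-8 on the same strand in the RefSeq table. For each of these genes the 5 libraries of a genotype lay wholly apart from the 5 of the other.

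All 4 genes lie on chromosome V in the RefSeq table of WBcel235, where 19.8% of the tested genes lie, and ZK228.3 and ZK228.4 are neighbours there. Of the detoxification genes, 0 were called in DMSO by edgeR: 0 of 61 P450, 0 of 60 UDP-glucuronosyltransferase and 0 of 32 glutathione S-transferase genes were called, with 9, 5 and 1 at unadjusted p under 0.05. DESeq2 called 2, 0 and 1 of them and limma-voom 0. Of all 13795 tested genes 575 were at unadjusted p under 0.05, a smaller share than the 9 of 61 P450 genes. The 30 genes with a smaller response in nhr-131 had a median log2 difference of 0.0157 in DMSO, with 0 called by edgeR, 8 at unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. They went both ways, 15 of them below 0, and the 8 of 30 were a larger share than the 575 of all 13795 genes. Picking genes by a smaller response pushes this DMSO difference upward, because it enters the difference of effects with the opposite sign. A lower level in DMSO may thus be masked. Some with large losses tended lower already in DMSO, without a call: cyp-13A4 (-3.04, SE 0.77), ugt-19 (-1.73, SE 0.49), ZK742.3 (-1.61, SE 0.44) and cyp-13A5 (-1.04, SE 0.47), with adjusted p between 0.674 and 0.985 and unadjusted p under 0.05. For cyp-13A4, ugt-19 and ZK742.3 this rested on the younger libraries a and c of wild type. Libraries b, d and e lay near the nhr-131 means of 0.731, 11.1 and 10.4 CPM, as given under the other observations. Camera called genes of oxidative phosphorylation up (31 genes, median 0.15, adjusted p = 0.02) and muscle markers down (25 genes, -0.11, adjusted p = 0.00918), each with 0 genes called, and both had adjusted p = 0.958 with an estimated correlation. The mean age scores differed by 0.00387. The count of 4 genes was 11 with DESeq2, 16 with the age covariate and 11 without the 6 younger libraries, each with all 4 among them.

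**Figure D4:**
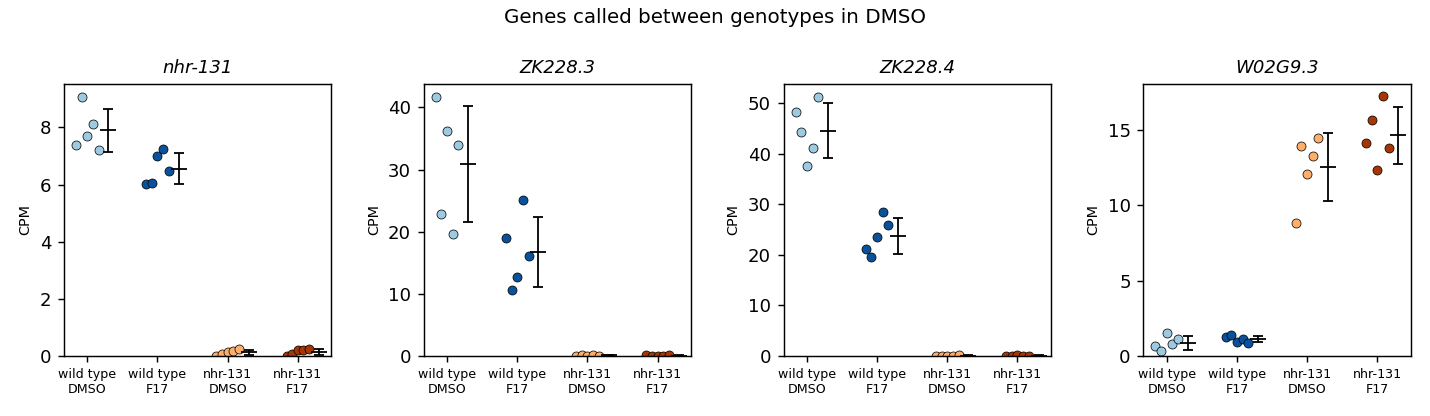
CPM of nhr-131, ZK228.3, ZK228.4 and W02G9.3 in each library (y axis) by group (x axis), 1 panel per gene; points are libraries and bars are the mean ± SD (n = 5). The first 3 lie near 0 in all nhr-131 libraries, and W02G9.3 averages 12.5 CPM or more there.

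The effect of F17 in wild type and the difference between genotypes in DMSO share the wild-type DMSO libraries. Across genes the Pearson r of the model's fold changes was 0.05 (jackknife SE 0.377), and 0.594 without the 6 younger libraries. From group means of log2 CPM r was 0, against a median of 0.526 (-0.32 to 0.892) in 1000 simulations with no effect. The covariance of these means was 9.9e-05 against a simulated mean of 0.0755. With the 5 shared libraries split into 2 and 3, the median r of 20 splits was -0.154 (-0.709 to 0.125), also from log2 CPM. Of the genes called for F17 in wild type, 0 were called between genotypes in DMSO by edgeR, where independent calls would share 0.00159 to 0.0231 per pair of directions. There 22 of the 106 higher and 4 of the 22 lower genes were at unadjusted p under 0.05, larger shares than the 575 of all 13795 tested genes. Of the 106 DESeq2 called 1 higher and 2 lower in nhr-131, of the 22 it called 0, and limma-voom called 0 of either.

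The fifth comparison set nhr-131 against wild type in F17, and 177 genes were called, 74 higher and 103 lower in nhr-131. Large differences were seen for genes of the F17 response: cyp-13A4 (-10.39, SE 0.96, adjusted p = 1.75e-06), ugt-20 (-6.12, SE 0.24, adjusted p = 7.66e-12), ZK742.3 (-6.95, SE 0.54, adjusted p = 1.71e-07), ugt-19 (-6.31, SE 0.59, adjusted p = 1.75e-06) and swt-6 (-4.80, SE 0.36, adjusted p = 1.12e-07) were lower. cyp-35B2 (2.23, SE 0.25, adjusted p = 2.46e-05) and F59B1.8 (2.18, SE 0.29, adjusted p = 0.000196) were higher. cyp-13A6, induced by a similar factor in both genotypes in the main fit, was lower as well, at 269 against 1150 CPM (-2.1, SE 0.45, adjusted p = 0.0252). In DMSO its difference was -1.84 (adjusted p = 0.674). Without the 6 younger libraries its rise with F17 in wild type was 9.75, against 8.20 with them, so the similar factor rests in part on those libraries. Of the 106 genes higher with F17 in wild type 46 were lower here and 7 higher. The 106 were picked with the wild-type F17 libraries that also enter this contrast, which by itself favours lower values in nhr-131. Of the 177 genes 63 were called for F17 in wild type, 33 for the difference of effects and 65 for either, and all 4 genes called in DMSO were among them. The age score was 0.549 higher in nhr-131 in this contrast. The count was 537 with DESeq2 (294 higher, 243 lower), 72 at an adjusted p under 0.01, 105 at an absolute log2 fold change of at least 1, and 107 in a fit of only these 10 libraries. It was 644 with the age covariate (325 and 319) and 1019 without the 6 younger libraries (650 and 369), so the larger share of lower genes was not kept. It was 90 without library b, and 99 without d, of wild type with F17, and 92, 86, 449 and 83 without a, b, c and d of nhr-131 with F17.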

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

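The counts of splits were planned before the data were examined, as were the comparisons, gene lists and rule for naming genes; the tests of developmental age, of the ZK228 genes and of 1 weaker response were chosen only after the results were seen.

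Some genes gave a different response to F17 in the genotypes, by a test of the difference itself: 34 genes were called, and the median signed difference over the genes called for the mean effect was -0.41. The differences of log2 fold change, nhr-131 minus wild type, were 2.26 for cyp-35B2, 2.09 for E02C12.6, 1.98 for F59B1.8 and 0.83 for ugt-26 on the higher side. On the lower side they were -7.35 for cyp-13A4, -5.79 for ugt-20, -5.34 for ZK742.3, -4.58 for ugt-19, -4.56 for swt-6, -3.92 for cyp-13A8, -3.56 for C53B4.3, -3.16 for cyp-13A5 and -2.97 for F12E12.11. The smaller ones were -2.38 for gst-7, -2.33 for ugt-12, -1.59 for cdr-4, -1.35 for gst-5 and -1.13 for F14B4.2.

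The loss of one part of the F17 response in nhr-131 beside another part still induced was weighed against 2 technical or simpler readings. One weaker response shared by all genes is argued against: with a constant share of 0.79 of the wild-type effect, 69 of the 142 genes called for the mean effect (48.6%) lay over 2 standard errors away, 31 above and 38 below. A difference in developmental age is argued against as the whole cause, since the 34 genes kept a median absolute difference of 105% of its size with the age covariate. A direct or indirect need of these genes for nhr-131 remains a hypothesis. Other lesions of the strain, such as a possible one at the ZK228 genes, stay open and were not tested.

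ZK228.3 and ZK228.4 were nearly without counts in nhr-131, with 8 and 5 counts over the 10 mutant libraries against 4664 and 6578 in wild type. A lesion in the mutant strain that removes both genes is a candidate explanation: the higher of them stood at 0.171% of wild type. The nearest tested gene on one side, Y51A2D.18, was not called (adjusted p = 0.985 in DMSO). ZK262.3 on the other side, at 1.55 CPM in wild type, kept 217 counts over the mutant libraries against 302 in wild type. Of the 217, 129 came from 1 library. ZK262.3 was thus not nearly without counts as the ZK228 genes were. Its fold change in DMSO was too uncertain to tell a smaller loss (log2 fold change -0.85, SE 1.4), so the exact extent on that side stays open. Loss of regulation by nhr-131 cannot be told apart from it, as the lower gene stood at 0.0863% of wild type and no strain in the series carries 1 change without the other.

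The third pattern was 112 genes that differed between genotypes in F17 without a call for F17 in wild type or for the difference, 56 higher and 56 lower in nhr-131. A difference in developmental age between the groups, as far as the score measures it, is argued against as the whole cause. With the age covariate the median absolute log2 fold change of the 112 genes was 91.2% of that without it. That all 112 were still called adds little, because the covariate also lowered the biological coefficient of variation from 41.1% to 26.5%. The score follows the L4-to-adult transition and dpy-7, a cuticle collagen gene of the moulting cycle, correlated with it within groups at r = 0.24 only, so a difference in moult phase may remain and was not tested. A biological difference between genotypes in F17 also stays open.

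For each comparison the count of called genes was set beside 100 splits of the libraries, the real one included. The share of splits was under the planned 0.05 for all 6, without correction for the number of comparisons. Where 3 or 4 splits reached the real count, 100 splits are too few to exclude chance. In wild type 2 splits gave as many genes as the real 128 (highest other 557), in nhr-131 1 (real 66, highest other 38), and for the difference of effects 4 (real 34, highest other 3266). For nhr-131 against wild type 4 splits gave as many in DMSO (real 4, highest other 1720) and 3 in F17 (real 177, highest other 1418), and for the mean effect 3 (real 142, highest other 3197). Splits that call several times the real count point to a structure of the samples. The 1 split with the highest count parted the age score by 0.866 in wild type, -1.57 for the difference, -0.824 in DMSO, 1.11 in F17 and -0.912 for the mean effect, against -0.302, 0.545, 0.00387, 0.549 and -0.0291 for the real groups. Age does not account for all of this: in DMSO a split with 226 genes parted the score by -0.0422, and splits that parted it by -0.887 in wild type, 0.942 in DMSO and 1.06 in F17 called 0 genes.

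Single libraries lay far from the other 4 of their group in 23 of 252 groups tested, over 60 named genes and 3 library measures, where chance alone gives about 1 in 20. Ribosomal RNA genes took 22.5% of the counts in library a of wild type with F17. The L4-to-adult score was -1.5 in library c of nhr-131 with DMSO. Library c of nhr-131 with F17, a younger one, stood apart for cyp-14A4 (151 CPM), F44G3.2 (182 CPM), ugt-12 (95.5 CPM), pgp-1 (151 CPM), pgp-9 (741 CPM), nhr-142 (14.4 CPM) and ZK228.4 (0.0977 CPM). Library c of nhr-131 with DMSO did so for cyp-35C1 (41.5 CPM), cyp-35A4 (0.295 CPM) and ugt-16 (34.4 CPM), library a of that group for clec-51 (58.9 CPM) and folt-2 (289 CPM), and library e for ZK228.4 (0.157 CPM). In wild type with DMSO, library b stood apart for ugt-61 (24.1 CPM) and clec-206 (2.5 CPM) and library e for cyp-35B2 (0.338 CPM). In wild type with F17, library d stood apart for E02C12.6 (5.46 CPM) and cyp-13A8 (4.95 CPM) and library a for ugt-19 (945 CPM). In nhr-131 with F17, library a stood apart for ugt-19 (12.1 CPM) and library e for ugt-20 (2.98 CPM).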

How the results depend on the processing

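The age covariate, leaving out the 6 younger libraries, the block by letter and leaving out ribosomal RNA genes were chosen only after the data were seen; the other settings were planned. Of the values for named genes under these settings, 1171 of the wild-type ones, 716 of the nhr-131 ones, 494 of those for the difference and 132 of those in DMSO kept direction and side of the threshold, while 148, 37, 113 and 0 lost the call. The calls lost under most settings were folt-2, pgp-3 and F42A10.7 in wild type, gst-8 in nhr-131, and cyp-13A5, E02C12.6, F59B1.8 and cyp-13A8 for the difference. Where a cause is not named, the cause was not tested.

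With DESeq2's Wald test the counts of called genes became 197 in wild type, 52 for the difference, 11 for genotype in DMSO and 537 for genotype in F17. With the age covariate they were 254 in wild type, 116 in nhr-131, 61 for the difference, 16 in DMSO, 644 in F17 and 270 for the mean effect, with a biological coefficient of variation of 26.5% in place of 41.1%. Without the 6 younger libraries they were 906, 140, 116, 11, 1019 and 496 in that order, and the correlation of the wild-type effect with the genotype effect in DMSO was 0.594. Those libraries were picked on the variation within groups, which lowers the remaining spread by construction, so the higher counts depend on that choice. The age scores of the remaining libraries with F17 also still differed, 0.0977 in wild type and 0.621 in nhr-131. At an adjusted p under 0.01, stricter by construction, 14 genes remained for the difference and 72 for genotype in F17, where an absolute log2 fold change of at least 1 left 105 and a fit of the 10 libraries, with fewer samples, gave 107.

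Without single libraries the counts ran from 109 to 150 in wild type, 60 to 76 in nhr-131, 19 to 31 for the difference, 4 to 5 in DMSO, 83 to 449 for genotype in F17 and 128 to 173 for the mean effect. The lowest and highest in F17 came without library d and without library c of nhr-131 with F17, and the lowest for the difference without c of wild type with F17 (19).

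Camera's calls of lists fell to 3, 4, 0 and 0 with an estimated correlation and to 4, 4, 0 and 0 with fry, in wild type, nhr-131, the difference and DMSO. Calls of gene classes fell from 9, 9, 11 and 4 to 2, 2, 0 and 0 with an estimated correlation, the 2 being the cyp and ugt classes. In DMSO the list calls were 6 with the age covariate and 6 without the younger libraries. Leaving out single libraries gave 1 to 11 list calls in DMSO: 1, 5, 4 and 4 without a, b, c and d of wild type, and 5, 11 and 5 without b, c and d of nhr-131.

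Directions turned in a few cases. Major sperm proteins in nhr-131 did so without library c of nhr-131 with DMSO (adjusted p = 0.655; range without single libraries 1.36e-08 to 0.655). Ribosomal proteins did so without library a of nhr-131 with DMSO, in nhr-131 (0.191; range 4.95e-06 to 0.191) and for the difference (0.923; range 7.97e-07 to 0.923), and for the difference without the younger libraries (0.66). L4-to-adult genes turned for the difference with the age covariate (0.57). That covariate is the mean z-score of the same 11 genes, so it takes out their shift by construction. The log2 effect of F17 on nhr-131 in the mutant, on 0 to 4 counts per library, was -0.04 with limma-voom, -0.02 without the younger libraries, -0.06 without a of nhr-131 with DMSO, and 0.00 and -0.07 without c and e of nhr-131 with F17 (range -0.07 to 0.43).

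A replicate block by column letter gave 123, 66, 20, 5, 187 and 145 genes in the order wild type, nhr-131, difference, DMSO, F17 and mean, with 18 of the 34 difference genes kept, and 7 gene class calls in DMSO. Whether the letters pair the libraries stays open: 7 of 20 libraries correlated best with their own letter, where chance gives 4. Residuals of equal letters had r from -0.681 to 0.818, with all 6 pairs of letter e at 0.162 to 0.56. The planned block by replicate number was not run: no paired analysis was possible by number because the columns carry letters that nothing maps to replicate numbers.

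In the library with the smallest TMM-scaled size 3 counts are 0.282 CPM. In simulated data 4 of 50 genes changed 1.5-fold and 33 of 50 changed 4-fold were recovered for F17 in wild type; recovery was not split by level, so the part of depth in it was not tested.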

Other observations

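The gene sets and genes of this part were chosen only after the data were seen, and so were their tests.

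With F17, some genes of the moulting cycle and cuticle were lower in nhr-131 than in wild type. The furrow collagen genes dpy-7 (log2 fold change -1.26, SE 0.27, adjusted p = 0.0261), dpy-2 (-1.25, adjusted p = 0.0217), dpy-10 (-1.35, adjusted p = 0.0267) and dpy-9 (-1.44, adjusted p = 0.029) were among them. So were noah-1 (-1.1, adjusted p = 0.041) and noah-2 (-1.16, adjusted p = 0.0478), which encode proteins of the apical extracellular matrix, lpr-3 (-1.39, adjusted p = 0.0363) and wrt-10 (-1.59, adjusted p = 0.0267). In the molting cycle list 4 of 26 genes were lower and 0 higher (median -0.618, camera adjusted p = 0.000278, and adjusted p = 0.82 with an estimated correlation). The collagen list leaned the other way, with 2 of 137 genes higher and 4 lower (median 0.333, camera adjusted p = 0.05, and 0.974 with an estimated correlation). DNA replication genes had a median of -0.489 without a called gene by edgeR (camera adjusted p = 2.58e-05, and 0.82 with an estimated correlation). The age score was 0.549 higher in nhr-131 in this contrast.

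With the age score as a covariate, the mean effect of F17 over both genotypes had 128 further genes, 44 higher and 84 lower. The ABC transporter gene mrp-3 rose by 1.1 (SE 0.086, adjusted p = 1.61e-08; 0.0797 without the covariate) and the gut esterase gene ges-1 by 0.76 (adjusted p = 8.69e-05). The lysozyme gene lys-4 fell by 0.71 (adjusted p = 0.00211), dod-24 by 0.72 (adjusted p = 0.000203), C17H12.8 by 0.69 and the intestinal acid phosphatase gene pho-1 by 0.37. In the innate immune list 1 gene rose and 5 fell of 32 (camera adjusted p = 0.0686, and 0.86 with an estimated correlation), and 6 of 29 ABC transporter genes rose and 0 fell (median -0.085, camera up at adjusted p = 0.0686, and 0.791 with an estimated correlation). Without the covariate 1 and 0 of the immune genes and 2 and 0 of the transporter genes were called.

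Many genes higher with F17 in wild type lie side by side. Of the 106, 32 neighbour another of the 106 among 13514 placed genes, against a median of 2 and a highest of 12 in 10000 random sets. Those sets were matched for expression level but not for gene family. Many of the neighbours belong to the same family. The excess therefore cannot be told apart from calls of families whose members lie in runs. The runs include gst-6, gst-7 and gst-8, cyp-13A4 to cyp-13A8, ugt-19 and ugt-20, and cyp-35A1 and cyp-35A2. Members of some runs differed in nhr-131: the log2 fold change there was 0.77 for cyp-13A4 and 0.86 for cyp-13A5, and 7.95 for cyp-13A6. Members of other runs moved alike there, such as ugt-19 and ugt-20 (0.45 and 0.36) and cyp-35A1 and cyp-35A2 (4.13 and 3.65). Close paralogs can share reads, so single levels within a run are uncertain.

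In wild type with DMSO, libraries a and c, the younger ones, held more of some F17-induced genes than b, d and e. cyp-13A4 was at 15.2 and 11.6 CPM against 1.02, 0.33 and 1.01 CPM, ZK742.3 at 64.2 and 59.5 against 11.6, 10.03 and 12.4 CPM, ugt-19 at 79.4 and 72.5 against 10.5, 9.22 and 11.9 CPM, and cyp-13A6 at 7.84 and 7.11 against 2.58, 0.90 and 0.90 CPM. cyp-14A4 was at 1.36 and 0.98 against 1.41, 0.76 and 1.97 CPM. In the younger library c of nhr-131 with DMSO, cyp-13A4 was at 0.63, ZK742.3 at 10.4 and ugt-19 at 9.27 CPM.

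oac-6, also on chromosome V, was at 7.52 ± 2.61 CPM in wild type and 19.4 ± 5.22 CPM in nhr-131 with DMSO (log2 fold change 1.37, adjusted p = 0.0826; SD, n = 5), and at 6.91 ± 2.26 and 29.7 ± 3.77 CPM with F17 (2.1, adjusted p = 6.34e-05).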
